A study of Mus musculus with 2 samples.

How the data were processed

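Gene expression was measured in mouse bone marrow-derived dendritic cells of the C57BL/6J strain on 2 biotin-labelled arrays. One culture was left unstimulated for 8 h and the other received 500 µg/ml laminarin for 8 h. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on a column, and amplified and labelled with a GeneChip whole-transcript terminal labelling kit.

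The deposited values were array intensities on a linear scale, summarised by the authors as a single value for each of 34365 probe sets. The background correction, the summary over probes and the scaling between arrays are not given in the sources used here. The values ran from 5.06 to 13412 on the unstimulated array and from 5.06 to 13927 on the laminarin array. Their medians were 63.7 and 64.1, so the arrays had a common scale in the values as deposited. No column of other values was used. The number of arrays, 1 per condition, limits the precision: no spread between samples could be estimated.

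The design had allowed for either log2 or linear values. As the values were linear, they were converted to log2(intensity + 16), and every difference given here is laminarin minus unstimulated on that scale. The added 16 makes the differences of dim genes smaller than the ratio of their intensities. The platform annotation gave exactly 1 gene symbol for 23521 probe sets, several symbols for 1814 and none for 9030. The last 2 kinds were left out of the gene comparisons. Entrez identifiers of 23328 of the single-symbol probe sets matched a RefSeq gene table of the mouse assembly GRCm38.p6, used for current symbols only, and other symbols were kept as annotated. This left 22180 genes. For 1082 genes with several probe sets, the probe set with the highest mean log2 level stood for the gene.

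A floor was set at the median over genes of the mean log2 level, 6.61, which is an intensity of 81.9. A gene counted as higher or lower when its difference was at least 1 log2 unit (2-fold) and its higher value was at or above the floor. With 1 array per condition this is a rule of size, not a test, and no p-value was computed. The spread of the differences between arrays is given as the standard deviation (SD) and as a robust SD, the median absolute deviation scaled to match the SD of a normal distribution. It holds the treatment effect and the technical error together.

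The comparison, the floor, the size rule, 26 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists comprised 17 of response genes, 8 of cell type markers and 1 of reference genes. They held 409 measured genes, 6 of them in several lists. For each list, the median difference of its measured members was ranked among 10000 random lists of the same size, matched gene by gene on 20 bins of mean level. A list was called outside the random range when its median lay outside the central 95% of the random medians. This percentile describes these arrays, since genes are not replicates of a treatment.

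The named genes were the 10 with the largest positive and the 10 with the largest negative difference among genes past 2-fold, the member with the highest and the member with the lowest difference in each list among those at or above the floor, and 22 genes fixed in advance. Predicted genes, non-coding RNAs, olfactory and vomeronasal receptors and antigen receptor segments were left out of the ranking and counted separately. Further list members given as examples were chosen after their values were seen.

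The alternatives were centring each array on its median, quantile normalization, an intensity-dependent loess, the mean over a gene's probe sets, only genes with 1 probe set, log2(intensity + 1), no floor, a floor at the 75th percentile, thresholds of 1.5-fold and 3-fold, a 2-fold threshold joined with 3 robust SDs of genes of similar level (10 bins), list members at or above the floor, list means, unmatched random lists, and a ranking with no symbols left out.

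The procedure was tested on simulated arrays with the levels of the 22180 genes. Of 100 genes moved by 1.5 log2 units, 99 were recovered, and of 100 moved by 2.0 log2 units, 100 were. None of 21980 unchanged genes was called. Of 100 unchanged lists of 20 genes, 4 lay outside the random range, and all 100 lists moved by 0.5 log2 units lay above it. The noise was normal, independent between genes, and had the robust SD of genes of similar level, at most 0.229. The absence of false calls was thus nearly fixed by the setting. Moved genes were drawn from those more than 1 log2 unit above the floor when unstimulated. The simulation checks the procedure and gives no error rate for the real arrays. Calculations were done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.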

Results

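Primary dendritic cells grown from mouse bone marrow were profiled on 1 array without stimulation and 1 array after 8 h with 500 µg/ml laminarin. Laminarin is a storage beta-glucan of brown algae, and Dectin-1, encoded by Clec7a, is a beta-glucan receptor of myeloid cells. The arrays form the mouse side of a study that asked whether an effect of laminarin tied to human Dectin-1 is also seen in primary cells. The human cells are not analysed here. There were no replicates, so every difference below compares these arrays, has no error between cultures and carries no p-value.

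Laminarin-treated cells had higher signals for inflammatory and interferon-stimulated genes. The largest difference was that of Saa3, an acute-phase serum amyloid A gene (probe set 17491193), with an intensity of 342 on the unstimulated and 5799 on the laminarin array, a difference of 4.02 log2 units. Cxcl3, a chemokine that attracts neutrophils (probe set 17438975), followed with 141 and 1621, a difference of 3.38. Cfb, which encodes complement factor B (probe set 17344064), had 203 and 1979, a difference of 3.19. Ifit1, an interferon-induced antiviral gene (probe set 17358832), had 218 and 2089, a difference of 3.17. Marco, a scavenger receptor of macrophages (probe set 17226327), had 310 and 2758, a difference of 3.09. The other 5 of the top 10 were Irf7 (2.89), a transcription factor of interferon responses, Ly6i (2.85), a surface protein of the Ly6 family, and the interferon-stimulated genes Rsad2 (2.85), Oasl2 (2.84) and Cmpk2 (2.84).

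Among the lower genes, Slc9a9, a sodium/proton exchanger of endosomes (probe set 17520396), had the largest difference, with 796 on the unstimulated and 179 on the laminarin array, or -2.05 log2 units. Scel, which encodes sciellin, had a difference of -1.88, and Cd300lg, a member of the CD300 receptor family, -1.60. Ptger3, a receptor for prostaglandin E2, had -1.54, and Hpgd, an enzyme that inactivates prostaglandins, -1.51. Hepacam2 had -1.52, the cytochrome P450 gene Cyp2ab1 -1.45 and Ifitm6 -1.41. Pparg, a nuclear receptor of lipid metabolism, had 523 and 197, a difference of -1.34. Emp1 had -1.35, but -0.69 when its probe sets were averaged.

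Of 11452 genes at or above the floor, 175 were at least 2-fold higher and 56 at least 2-fold lower on the laminarin array, together 2.02% of these genes. At 4-fold the counts were 31 higher and 1 lower, and 5 genes were 8-fold higher. Predicted, non-coding and receptor-family symbols made up 7 of the 175 higher and 10 of the 56 lower genes. Members of multicopy families described under other observations are among the lower genes. Before the floor was applied, 3 signals with 1 symbol of Astx and 3 of Vmn1r were at least 2-fold lower. The differences of genes at or above the floor had a median of -0.03, an SD of 0.35 and a robust SD of 0.23 log2 units, and 90.6% of them were smaller than 0.5. Across these genes, which are not independent replicates, the arrays had a Pearson correlation of 0.970.

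**Figure D1:**
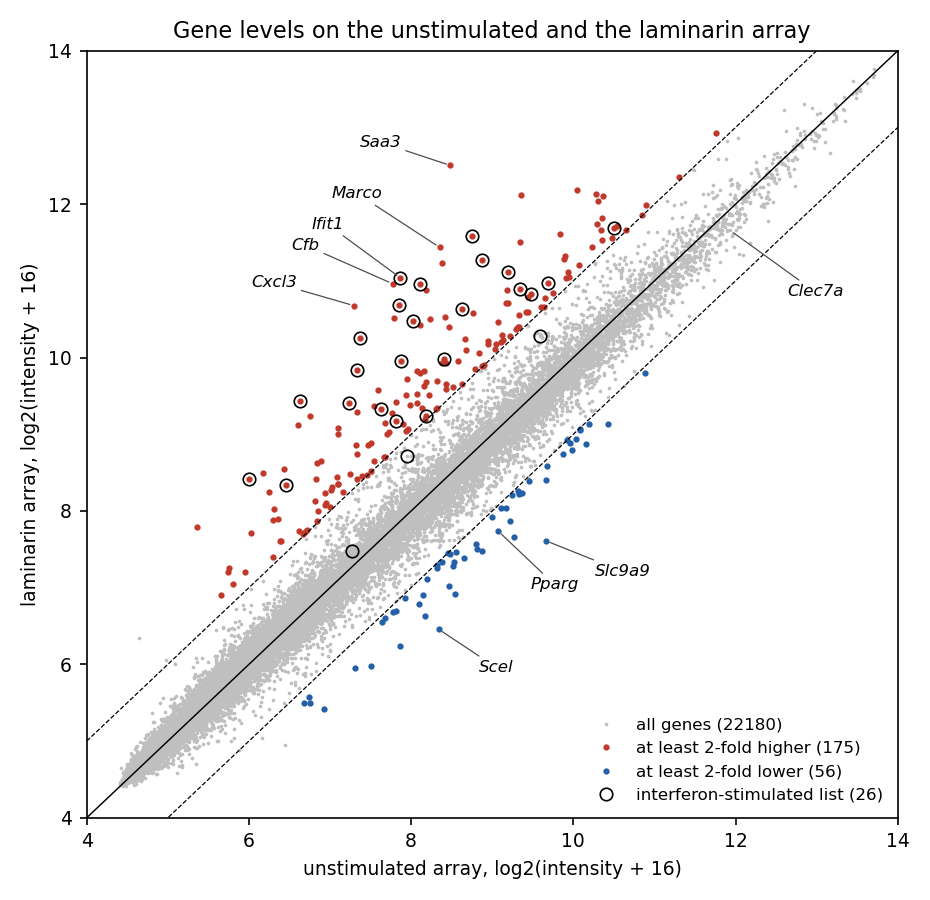
Each point is a gene, with log2(intensity + 16) on the unstimulated array on the x axis and on the laminarin array on the y axis; the solid line marks equal levels and the dashed lines 2-fold differences. Red points are the 175 genes called higher, blue points the 56 called lower, and open circles the 26 interferon-stimulated genes, 23 of which are called higher.

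The interferon-stimulated list had the largest median difference of the 26 lists. All 26 measured members had a positive difference, 23 were at least 2-fold higher and none was lower. The median was 1.96 log2 units, above all 10000 random lists. Besides Ifit1, the ubiquitin-like modifier Isg15 was higher by 2.51, the DNA and RNA sensor Zbp1 by 2.40 and the guanylate-binding protein Gbp5 by 2.17. The 3 members under 2-fold were Gbp3 (0.77), Irf9 (0.69) and Ifit3 (0.21). The signal of Ifnb1, which encodes interferon beta, was below the floor on both arrays, at 16.1 and 21.0.

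Genes of NF-kB and of cytokines and chemokines were also higher. Of 21 NF-kB targets and feedback genes, 20 had a positive difference, with a median of 0.61, above all 10000 random lists. At least 2-fold higher were Gadd45b (1.09) and Traf1 (1.08), while the feedback inhibitors Nfkbiz and Nfkbia differed by 0.65 and 0.43, and Tnip3 by -0.13. Among 23 cytokine genes, 5 were at least 2-fold higher and none lower. Il1b went from an intensity of 1302 to 4397 (1.74), Il1a had a difference of 1.69, Il6 went from 67.5 to 179 (1.23), Il12b from 229 to 513 (1.11) and Tnf from 1412 to 3012 (1.08). Il10 (16.2 and 17.0), Il23a (35.5 and 33.8) and Csf2 (27.6 and 36.9) stayed below the floor on both arrays, and Il18 had a difference of -0.29. The cytokine median was 0.20, above all 10000 random lists, and 0.43 over the 15 members at or above the floor.

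Of 20 chemokine genes, 5 were at least 2-fold higher and none lower, with a median of 0.49, above all 10000 random lists. The mean was 0.78. With Cxcl3, these were Cxcl10 (2.73) and Cxcl9 (2.12), which attract T cells, Ccl5 (1.85) and Cxcl2 (1.02). Cxcl2 fell short of 2-fold, at 0.997, when the arrays were centred on their medians. Cxcl1 differed by 0.96, and by 1.15 with log2(intensity + 1). The already bright chemokine genes Ccl17 and Ccl22 had differences of 0.08 and 0.63, and Ccl6 one of -0.14.

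**Figure D2:**
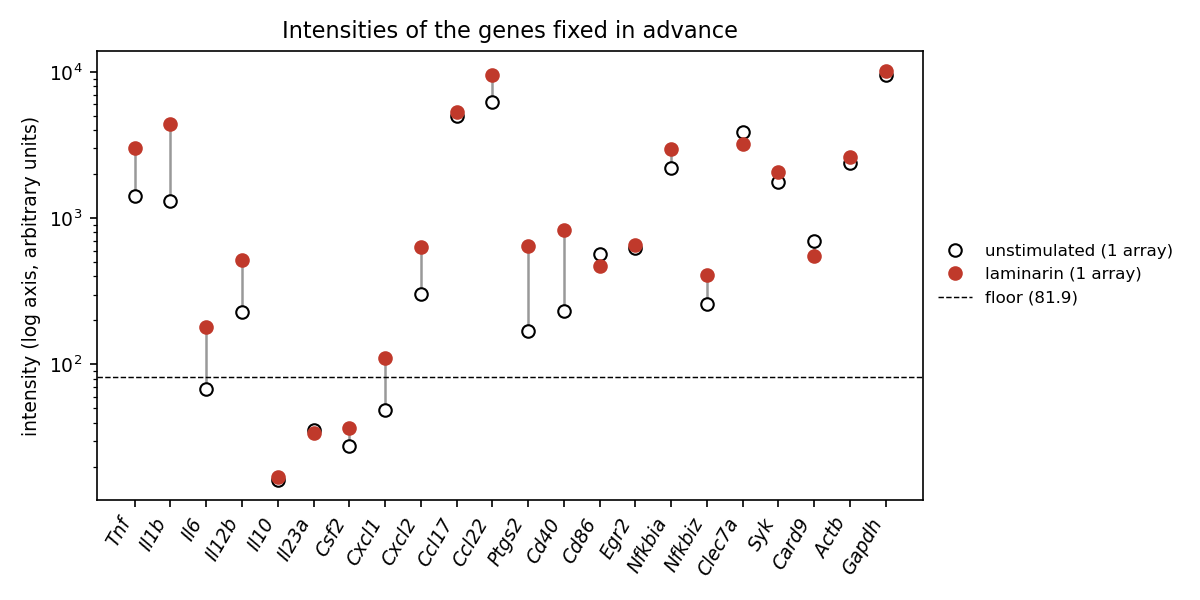
Intensity on a log axis (arbitrary units) of the 22 genes fixed in advance, with an open circle for the unstimulated array and a red circle for the laminarin array, joined by a line; the dashed line is the floor of 81.9. Il1b, Ptgs2 and Cd40 have the widest gaps, at 1.74, 1.83 and 1.76 log2 units, and Il10, Il23a and Csf2 lie below the floor on both arrays.

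The components of the Dectin-1 pathway showed no common difference. Of 18 measured members, none was 2-fold higher or lower, and the median of 0.01 lay above 8435 of 10000 random lists, inside the random range. Clec7a itself (probe set 17471541) had 3892 on the unstimulated and 3218 on the laminarin array, a difference of -0.27. The kinase gene Syk differed by 0.22 and the adaptor gene Card9 by -0.33. The extremes of the list were the kinase gene Src at 0.71 and Vav3 at -0.77. In the list of NFAT targets and immediate early genes, 1 of 21 members was 2-fold higher, Ptgs2 (cyclooxygenase-2), by 1.83. Egr2, an NFAT target, had 623 and 653, a difference of 0.07, and Nr4a1 had the lowest, -0.40. The median of that list was 0.10 and its mean 0.18, and the median lay above 9891 of 10000 random lists.

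Of 21 dendritic cell maturation genes, 18 had a positive difference and 4 were at least 2-fold higher. These were the costimulatory receptor Cd40 (1.76), the actin-bundling gene Fscn1 (1.35), Cd200 (1.11) and Pdcd1lg2 (1.09). The migration receptor Ccr7 differed by 0.96, while the costimulatory gene Cd86 had a difference of -0.26. The median was 0.61, above all 10000 random lists. The 12 genes of MHC class II presentation had none past 2-fold and a median of 0.00, above 7330 of 10000 random lists, with extremes of 0.47 for Ifi30 and -0.52 for Lgmn. Of 24 pattern recognition receptors and adaptors, Marco alone was 2-fold higher. Mrc1, the mannose receptor, had the lowest difference, -0.75. The median of 0.06 was above 9706 of 10000 random lists, inside the random range, and the mean was 0.22, above it.

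Genes of oxidative stress and of nitric oxide and itaconate metabolism were higher. Of 13 NRF2 and oxidative stress genes, 12 had a positive difference. The median was 0.60, above all 10000 random lists. Me1 (1.07) and the cystine transporter Slc7a11 (1.02) were 2-fold higher, and Mt1 was lowest at -0.17. Of 13 genes of nitric oxide, arginine and itaconate metabolism, 3 were 2-fold higher. Acod1, which makes itaconate, had 640 and 4417, a difference of 2.76, the arginine transporter Slc7a2 one of 1.18 and the nitric oxide synthase Nos2 one of 1.12. Odc1 was lowest at -0.24. That list had a median of 0.29, above 9998 of 10000 random lists, and a mean of 0.61. Of 16 glycolysis and hypoxia genes, Pfkfb3 alone was 2-fold higher (1.02, and 0.994 with centred arrays) and Pdk1 was lowest at -0.11. Their median was 0.19, above 9992 of 10000 random lists.

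The heat shock list and the list of endoplasmic reticulum and amino acid stress held no gene past 2-fold. The 10 heat shock genes had a median of 0.15, above 9890 of 10000 random lists, with Hspa1b at 0.81 and Hspe1 at -0.18. Their mean lay inside the random range. The 17 genes of the latter had a median of 0.09, above 9734 of 10000 random lists and inside the random range, with Mthfd2 at 0.73 and Atf4 at -0.07. Their mean was 0.17, above the random range.

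Cholesterol synthesis and cell cycle genes were lower as groups, without a member past 2-fold. Of 14 cholesterol synthesis genes, 13 had a negative difference, and their median of -0.36 lay above 0 of 10000 random lists. Cyp51 was lowest, at -0.79, and Srebf2 highest, at 0.09. Of 24 cell cycle genes, 2 had a positive difference, and the median of -0.32 also lay above 0 of 10000 random lists. The mitotic kinesin gene Kif11 was lowest, at -0.77, with the proliferation marker Mki67 at -0.57 and Top2a at -0.61, while the replication licensing genes ranged from -0.21 for Mcm7 to 0.16 for Mcm5. Of 15 LXR and PPAR-gamma lipid genes, 3 were at least 2-fold lower and none higher. With Pparg, these were the apolipoprotein gene Apoe (-1.08) and the fatty acid binding protein gene Fabp4 (-1.02), and the cholesterol exporter gene Abca1 was highest, at 0.70. That median of -0.17 lay above 444 of 10000 random lists, inside the random range, and the mean of -0.27 lay below it.

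**Figure D3:**
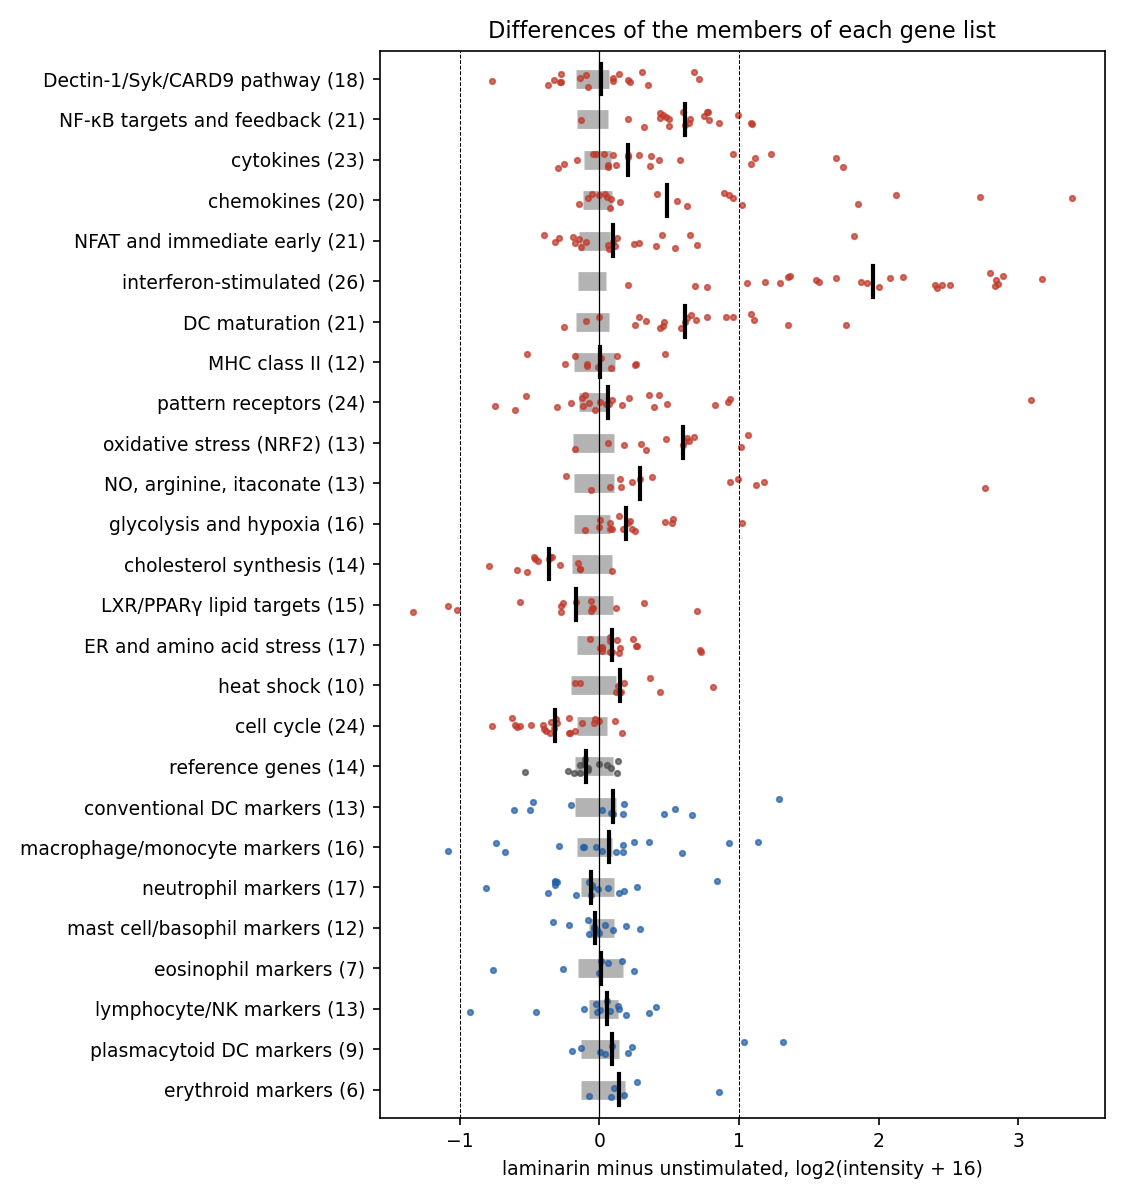
Difference in log2(intensity + 16), laminarin minus unstimulated, of each member (points) of the 26 lists, with the number of measured members in parentheses; black bars are medians, grey bands the central 95% of random list medians and dashed lines 2-fold differences. Red marks response lists, blue cell type markers and dark grey reference genes; the interferon-stimulated median of 1.96 lies farthest from its band.

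Of the 17 response lists, 10 had a median above the random range and 2 below it. None of the 8 cell type lists lay outside it in the main setting, but 4 of them lay above it under some alternatives. Conventional dendritic cell markers (13 measured) had a median of 0.10, with Btla at 1.29 and Irf4 at -0.50. Macrophage and monocyte markers (16 measured) had a median of 0.07, with Fcgr1, an Fc receptor gene, at 1.14 and Apoe at -1.08. Plasmacytoid dendritic cell markers (9 measured) had a median of 0.09. At least 2-fold higher among them were Bst2 (1.31), which is also interferon-inducible, and Spib (1.04), while Siglech was below the floor on both arrays and Ly6d differed by -0.13. Neutrophil markers (17 measured) had a median of -0.06, with Lcn2 at 0.84 and Cxcr2 at -0.37. The medians were -0.03 for mast cell and basophil markers (12 measured; Kit 0.10, Cpa3 -0.33), 0.01 for eosinophil markers (7 measured; Epx 0.16, Siglecf -0.77), 0.06 for lymphocyte and natural killer cell markers (13 measured; Cd8a 0.36, Prf1 0.14) and 0.14 for erythroid markers (6 measured; Car2 0.86, Epor -0.08). The 14 reference genes had none past 2-fold and a median of -0.09, above 2141 of 10000 random lists, with Actb at 0.14, Gapdh at 0.08 and Hprt lowest at -0.53.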

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

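The tests of explanations in this part were chosen only after the result was seen.

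Probe sets outside the gene comparison differed in both directions, and more of them were lower than higher on the laminarin array. Of the probe sets with no gene symbol, 13 were at least 2-fold higher and 52 at least 2-fold lower on the laminarin array. The largest positive difference, 3.44 log2 units, was that of probe set 17411147, with intensities of 110 and 1352. Of the probe sets with several gene symbols, 9 were at least 2-fold higher and 121, which hold 54 distinct signals, at least 2-fold lower. Of the 121, 93 carried symbols of the multicopy families seen first, which are described under other observations. The largest positive difference among probe sets with several symbols, 1.72, was that of probe set 17248911 (Olfr56 and Ifi47), with intensities of 89.4 and 331. Both probe sets were singled out after their values were seen.

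The interferon-stimulated genes had the highest median difference of the fixed lists, 1.96. Scaling between the arrays would have to bring the list into the random range, but its lowest median under the other 3 scalings was 1.94. The median difference of all genes was -0.02 with centring, 0.01 with quantile normalization and 0.00 with loess. The arrays thus already had a common scale, and this outcome was nearly fixed. Signal shared between near-identical paralogs would be limited to families such as Ifit, Oas, Mx, Gbp and Trim, but the 14 members outside these 5 families had a median of 1.74 and 13 of them were 2-fold higher. A microbial ligand of another receptor in the laminarin preparation stays open and cannot be told apart from an action through Dectin-1: the NFAT and immediate early list, at 0.0965, decides nothing, and an array with the receptor removed is not analysed here. A response to laminarin remains a hypothesis beside it, and neither differences between cultures without treatment nor a changed mix of cells, beyond the cell type medians of the report, was tested.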

How the results depend on the processing

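All alternatives were fixed before the data were examined. Under no alternative did a called result change sign. Of 506 alternative values of named genes, 502 moved by less than the robust SD of genes of similar level. Of 208 list values, 185 moved by less than the SD of the random lists, and of 234 percentiles 220 kept their side of the random range. Part of this was fixed by the settings. Most named genes have 1 probe set, so averaging probe sets or keeping only such genes could not move their values. Centring shifts all differences alike, so it could not change a percentile. All 175 higher genes stayed 2-fold higher under quantile normalization and loess, 166 with centred arrays and 165 with averaged probe sets. All 175 also did with log2(intensity + 1), but a smaller added constant can only widen a positive difference. The number of lower genes shared with the main setting was 56 with centred arrays and 48 under quantile normalization and loess. Of 85 named genes, 4 crossed 2-fold under some alternative (Cxcl1, Cxcl2, Emp1 and Pfkfb3).

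Counts moved with the thresholds that define them. At 1.5-fold there were 438 higher and 339 lower genes, at 3-fold 58 and 5 (the latter Slc9a9, Scel, Mir101c, Vmn1r103 and Cd300lg), and with a floor at the 75th percentile 35 lower genes. With log2(intensity + 1) the median was 0.359 for cytokines, 0.617 for chemokines and 2.06 for interferon-stimulated genes, and under loess 0.253 for cytokines and 2.02 for interferon-stimulated genes. Over members at or above the floor it was 0.429 for cytokines and 0.594 for chemokines, and the stress list of the endoplasmic reticulum reached percentile 98.6. The mean of members was 0.428 for cytokines, 0.780 for chemokines, 0.181 for NFAT and immediate early genes, 0.215 for pattern receptors (percentile 99.5), 0.493 for oxidative stress, 0.613 for nitric oxide and arginine, -0.271 for LXR and PPAR-gamma lipid genes (percentile 0.09) and 0.173 for endoplasmic reticulum stress (percentile 97.7), and heat shock fell inside the random range (percentile 96.0). The lipid list reached percentile 0.30 among unmatched random lists, and endoplasmic reticulum stress 98.1 under quantile normalization and 97.525 under loess. Of the cell type lists, conventional dendritic cell markers lay above the random range under quantile normalization (percentile 97.58), loess (97.54) and over members at or above the floor (99.3), macrophage and monocyte markers over members at or above the floor (99.0), and the means of plasmacytoid dendritic cell (99.5) and erythroid markers (98.2) did so too. Beyond the thresholds and summaries themselves, the cause was not tested. Dim genes are limited by the signal: the robust SD ran from 0.088 in the lowest of 10 bins of mean level to 0.229 in the widest, and an added 16 compresses differences there.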

Other observations

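The 10 gene lists of this part, their subsets, and the tests of dilution and of male cells were chosen only after the results were seen.

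Further interferon-inducible gene families were higher on the laminarin array. Of 6 Schlafen genes, 5 were at least 2-fold higher, with Slfn4 at 2.52, Slfn5 at 2.27 and Slfn1 at 2.12, and a median of 1.75. Of 13 guanylate-binding and immunity-related GTPase genes, 2 of which (Gbp5 and Gbp3) also belong to the fixed interferon-stimulated list, 6 were 2-fold higher, among them Gbp5 (2.17), Igtp (1.61) and Irgm2 (1.58), with a median of 0.94. Of 16 genes of MHC class I presentation and the immunoproteasome, the transactivator gene Nlrc5 was 2-fold higher (1.46), followed by Tapbp (0.97), Tap1 (0.92) and Psmb10 (0.88), with a median of 0.51. Each median lay above all 10000 random lists. The MHC class II list had a median of 0.00.

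Prostaglandin genes went both ways. Of 19 eicosanoid genes, Ptgs2 (1.83) was 2-fold higher, with the prostaglandin E synthase gene Ptges at 0.98, while Ptger3 (-1.54), Hpgd (-1.51) and Hpgds (-1.23) were 2-fold lower. The median was -0.18, above 70 of 10000 random lists. Of 15 acute-phase and complement genes, Saa3, Cfb and Hp (1.45) were 2-fold higher, with a median of 0.34, above all 10000 random lists, and of 0.84 over the 9 members at or above the floor. Saa3 and Cfb, like Ptger3 and Hpgd of the eicosanoid list, had been seen before the lists were written. Of 19 genes of matrix turnover, Lox (2.32), Mmp14 (2.17), Serpinb2 (1.82) and Mmp25 (1.13) were 2-fold higher, with a median of 0.09, above 9817 of 10000 random lists. Of 16 genes of alternative activation, Cd300lg, Pparg, Il1r2 (-1.29) and Fabp4 were 2-fold lower and Pdcd1lg2 and Socs1 (1.04) higher. Among the other members, Mrc1 had -0.75, Chil3 -0.26 and Arg1 0.08, and Retnla was below the floor on both arrays. The list had a median of -0.42, above 0 of 10000 random lists, but several members had been seen to be lower before the list was written. The 28 ribosomal protein genes had a median of -0.07, above 1281 of 10000 random lists.

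The 26 mitosis genes had a median of -0.52, above 0 of 10000 random lists, with Kif23 lowest (-1.19). The median was -0.02, above 5791 of 10000, for 15 genes of replication licensing and initiation, called licensing genes below. They include the initiation genes Mcm10, Cdc45, Gins1 and Gins2 and the polymerase clamp gene Pcna. Of the mitosis and licensing genes, 13 and 7 belong to the fixed cell cycle list, in which the split had been seen. That fixed list also holds the DNA synthesis genes Rrm2 (-0.39), Tk1 (-0.30) and Tyms (-0.22), which are in neither. Scaling would have to bring the mitosis list into the random range, but its median nearest to 0 under the other 3 scalings was -0.458. That outcome, too, was nearly fixed by the common scale of the arrays. Dilution of dividing by non-dividing cells would lower both lists alike if both were equally confined to dividing cells, which was not tested. Their medians differed by -0.497 (SD from random lists 0.087), and by -0.63 (SD 0.12) over the 13 mitosis and 8 licensing genes outside the fixed list. The lists thus did not fall equally, but without that condition the gap cannot decide on dilution. Dilution stays open, and no biological explanation was tested.

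Some multicopy families with little expected expression in dendritic cells had lower signals on the laminarin array: in 3 families seen first (Vmn1r, the Sly and Ssty genes, and Snord116), 48 of 49 distinct signals of probe sets with 3 or more symbols were lower, with a median of -1.15. A further family seen first, Astx, was lower in its probe sets with 1 symbol (3 signals, median -1.25), and the Sly and Ssty genes had medians of -0.90 with 1 symbol (3 signals) and -1.03 with 2 symbols (7 signals), whereas 180 such signals of Vmn1r had a median of -0.02. The probe sets with 3 or more symbols stayed at a median of -1.12 or lower under the other 3 scalings, an outcome nearly fixed by the common scale of the arrays. A different share of male cells would spare the Vmn1r genes, whose median in these probe sets was -1.19, so it alone cannot account for that family. Vmn1r had already been seen to be lower, so this was no independent test. For the Sly and Ssty genes of the Y chromosome, a different share of male cells stays open. Genomic DNA in the unstimulated sample could raise signals with copy number, and other silent families were examined for it. Probe sets with 3 or more symbols, found in 6 of these families, had a median of -0.321 (51 signals, 47 lower), between the bounds set beforehand. Those of them with 5 or more symbols had a median of -0.380 (32 signals, 32 lower). The medians were 0.005 for 26 signals with 2 symbols and 0.00 for 1299 signals with 1 symbol. Many of these signals were dim, where the added 16 shrinks differences. The 15 Slx and Xlr signals with 5 or more symbols had median intensities of 18.1 unstimulated and 11.1 with laminarin. The 1107 Olfr signals with 1 symbol, at 15.8 and 15.7, could show little of an effect of genomic DNA. As the tested median lay between the bounds and may be compressed, genomic DNA and a change in transcription cannot be told apart here.

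Of all probe sets, 610 (1.78%) had identical values on both arrays, among them those of Ccl4, at 370 on each; the share was 3.64% in the lowest of 10 bins of mean level and 0.09% in the highest.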
